A study of Homo sapiens with 4 samples.

How the data were processed

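Polyadenylated RNA from A2780 cells was measured in 4 libraries, 2 from control cells and 2 from cells given GD-07. Per the labels, the cells were grown in DMEM with serum, mRNA was enriched with oligo(dT) beads, libraries were made with a NEBNext Ultra II kit, and both ends of each fragment were read for 150 bp. The deposited table gives TPM per gene symbol for each library, made by the authors before deposit. Per the submitters' processing notes, kallisto, Subread, limma 3.60.4 and the build GRCh38 were used, but the role and order of each are not given in the sources used here. How transcripts were combined per symbol is likewise not given in the sources used here.

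The table held 35371 gene symbols, of which 8598 were listed at 0 in every library. The columns summed to 918209, 917531, 912781 and 918646 TPM for control replicates 1 and 2 and GD-07 replicates 1 and 2, so 8.18%, 8.25%, 8.72% and 8.14% of a full TPM total lay outside the table. TPM keeps no read depth, so the depth behind each value is unknown, no interval for counting error can be given, and a value of 0 does not show absence. A share taken by a few abundant transcripts lowers all other TPM values of that library, which is why other scalings were tried. Higher and lower therefore refer to a gene's level relative to the other transcripts of its library. A change of total RNA shared by all genes cannot be seen. Symbols were matched to GENCODE 29 on GRCh38 by name, which found 27677 of the 35371 symbols and 12223 (93.6%) of those kept for testing. Of the kept symbols 11613 were annotated as protein-coding, and 15 repeated the 4 values of another symbol. Coordinates come from that annotation, whose release may differ from the one the authors used.

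Samples were grouped by the labels, and the comparison, its test, the gene lists and the rule for named genes were fixed before the data were examined. Genes with a mean of at least 1 TPM over the 4 libraries were kept (13063). Values were transformed as log2(TPM + 1), and the groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend, two-sided), with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Fold changes are on the log2(TPM + 1) scale, which understates changes of low genes, and errors of fold changes are limma's moderated standard errors. With 2 libraries against 2, the smallest p an exact two-sided permutation test can give is 0.333, so no exact test was run per gene. When a library was left out, the remaining single library of its group was assumed to vary like the other group. The pair kept whole then supplied all of the residual spread, and the control pair lay closer together (r = 0.993) than the GD-07 pair (r = 0.982). Counts of calls and p-values in these fits therefore depend on which pair was kept whole, not only on the library left out.

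The 39 fixed lists cover MYC and its reported targets, metabolism, mitochondrial and ribosomal genes, cell cycle, stress responses, lipid synthesis, signalling, autophagy and lysosome, cell state and markers of other cell types. Those with at least 5 kept members (31) were tested with limma's camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry. With an estimated correlation, camera has only the few residual degrees of freedom of 4 libraries, so not passing there is weak evidence against a shift. The shorter lists are described by values. No member of the lists of nuclear-retained noncoding RNAs and of snoRNA host genes was matched in the table, so those were not analysed here. Counts adjusted over the list alone apply the same adjustment to the members of a list by themselves.

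Named genes follow a rule with 4 parts. The first takes the 8 genes with the largest change in each direction among those that passed, whose groups did not overlap and which had a value above 0 in each group. The second takes MYC, MAX, MYCN, MYCL and 9 genes of glucose uptake, glycolysis and lactate export whatever their values. The third takes up to 4 members of each list, those past the threshold with the largest change, or otherwise the 2 with the smallest p. The fourth takes the 3 most abundant genes past the threshold in each direction. SFN and FGB were the only kept members of their lists. Values of some genes that the rule takes are not reported here.

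The procedure was tested on simulated data with the same 13063 genes, the same group sizes and 200 changed genes, in 5 simulated sets. It recovered 47.6% of 2-fold and 98.0% of 4-fold changes, 6.49% of its calls were unchanged genes, all 5 lists given a shift were called, and none of 185 random lists were. Every shifted list had the same size, and all its members moved by the same amount. Recovery of shorter lists or smaller shifts was therefore not tested. The simulated genes varied independently of each other. In the real lists the estimated correlation was 0.127 for MYC-activated growth and nucleolar genes and 0.979 for mitochondrially encoded transcripts. False list calls from such correlation were therefore not tested. The settings varied were pseudocounts of 0.1 and 5 TPM, no filter and a filter at a mean of 5 TPM, median-ratio and quantile scaling, removal of mitochondrially encoded genes, limma without the trend or with a robust prior, the replicate number as a block, leaving out each library, stricter thresholds, and camera on ranks. A correction of each library for GC content by loess (span 0.5), protein-coding genes alone and the collapse of symbols with identical values were chosen after seeing the data. Errors of list medians are from 2000 bootstrap resamples of the members. They treat the members as independent and do not measure variation between libraries.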

Results

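RNA-seq was used to measure transcript levels in A2780 cells, an established human ovarian cancer cell line grown as a monolayer, with or without GD-07, a compound that the series text describes as a small-molecule inhibitor of MYC. MYC is a transcription factor that drives growth, ribosome production and metabolic genes. The labels place 2 libraries in the control group and 2 in the GD-07 group, and give neither the dose nor the time of treatment. The series text names a vehicle control, whereas the sample labels give the controls no treatment. The values were deposited as TPM, transcript abundance scaled to each library's total, for 35371 gene symbols, a unit that keeps no sequencing depth, so the depth of each library is unknown and no counting intervals or detection floors are given. The labels do not say whether the replicates came from separate cultures, so p-values measure only the spread between these 4 libraries, which may be technical.

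The control libraries resembled each other more (Pearson r = 0.993 across genes on the log2 scale) than the GD-07 libraries did (r = 0.982). Control replicate 2 and GD-07 replicate 1 correlated at r = 0.983, slightly above the GD-07 pair. The first principal component held 63.2% of the variance and separated the groups, with scores of -27.5 and -20.6 for the controls and 15.2 and 32.8 for the GD-07 libraries. The second held 27.5% and set replicates of a group apart, with scores of 13.6 and -7.71 for the controls and -23.2 and 17.3 for the GD-07 libraries. GD-07 replicate 2 stood apart in its composition. Mitochondrially encoded transcripts made up 6.52% of its TPM, against 2.52% in GD-07 replicate 1 and 4.36% and 3.72% in the controls. Its 10 most abundant entries held 11.0% of TPM, compared with 7.06% to 7.08% in the other libraries. The entry with the highest mean, RP11-777B9.5, which was not matched to GENCODE 29 and was named after its values were seen, held 4.25% of TPM there, against 0.831% in GD-07 replicate 1 and 1.16% and 1.01% in the controls. In GD-07 replicate 2, 14683 entries were listed at 0, compared with 11598 and 11688 in the controls and 12346 in GD-07 replicate 1.

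The question posed by the series is how GD-07 alters gene expression in these cells, with glycolysis under MYC as the named interest. MYC mRNA itself was lower with GD-07, at 26.4 ± 3.89 TPM (SD, n = 2) against 76.7 ± 13.04 TPM in the controls (SD, n = 2). The individual values were 86.0 and 67.5 TPM in the controls and 29.1 and 23.6 TPM with GD-07. MYC (ENSG00000136997) lies on the plus strand of chromosome 8 from 127735434 to 127741434 in GRCh38, and its log2 fold change was -1.50 ± 0.18 (limma standard error, adjusted p = 0.0109). MAX, the dimerization partner of MYC, fell from 56.5 ± 4.57 to 35.8 ± 2.22 TPM (SD, n = 2 each), a log2 fold change of -0.64 ± 0.15 (limma adjusted p = 0.0465). MYCL had a log2 fold change of -0.05 (limma adjusted p = 0.907), and MYCN was listed at 0 in all 4 libraries. Of the 12 kept members of the MYC network list, 2 fell and 10 did not pass, or 3 lower when adjusted over the list alone, and the list as a whole did not pass (camera adjusted p = 0.0705, and adjusted p = 0.802 with an estimated correlation). Without control replicate 2 the list passed (camera adjusted p = 0.0157). The call of MAX ended without control replicate 1 (limma adjusted p = 0.318), without control replicate 2 (0.0817), under median-ratio and quantile scaling, with a pseudocount of 0.1 TPM and without limma's trend.

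Across the 13063 genes with a mean of at least 1 TPM, 681 passed limma's test at an adjusted p under 0.05, of which 264 were higher and 417 lower with GD-07. Protein-coding genes made up 588 of these calls, 222 higher and 366 lower. At an unadjusted p under 0.05 there were 3239 genes, and 265 of the calls were at least 2-fold on the log2(TPM + 1) scale, which understates changes of low genes. Without limma's intensity trend 385 genes passed, and of the named genes MAX, PKM, LDHA, PFKP, SORD, GRWD1, MCM2, EIF4E, MTHFD2, PAICS, BUB1B, MKI67, WARS, CHAC1, HSPA5, TM7SF2, FADS2, BID, NKRF, CTD-2510F5.6, TMSB10, EIF1, LAMB2 and EIF5A then did not. The split depended on scaling, with 383 higher and 395 lower after quantile normalization. The count was 286 without control replicate 1, 719 without control replicate 2, 2308 without GD-07 replicate 1 and 1527 without GD-07 replicate 2. In a fit without 1 library the spread comes from the other group's pair alone, so these counts do not measure how much rests on the library left out. With no filter on low values, none of 26773 genes passed in limma (smallest adjusted p = 0.219, with 3970 at an unadjusted p under 0.05), so every call below holds only among genes kept by the filter.

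**Figure D1:**
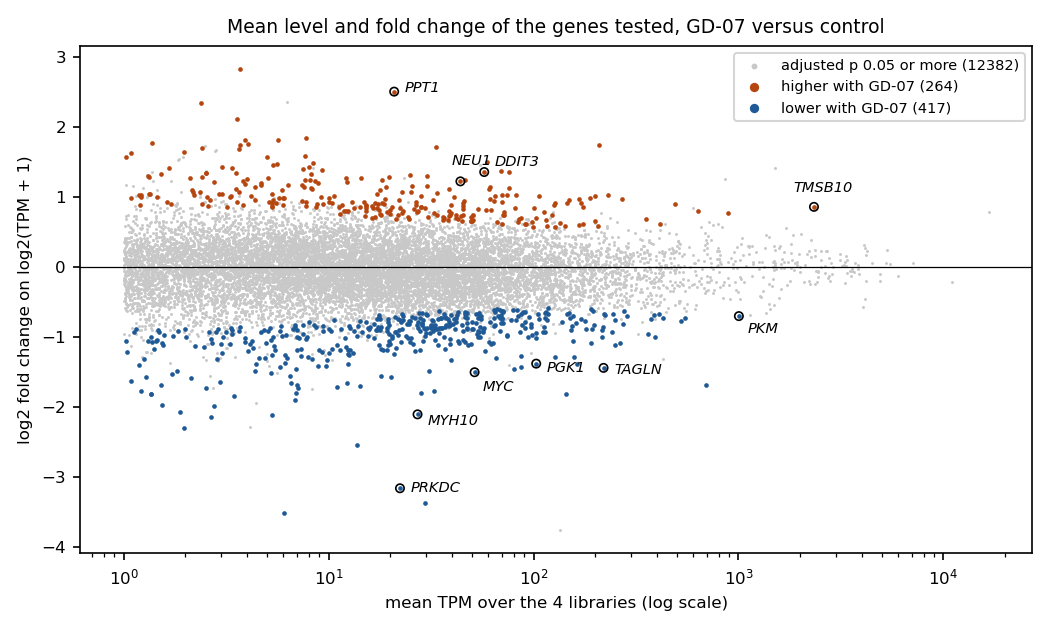
Mean TPM over the 4 libraries (x axis, log scale) against the log2 fold change on log2(TPM + 1) (y axis) for the 13063 genes tested, with the 264 higher and 417 lower genes in colour. MYC lies at -1.50, PRKDC at -3.16 and PPT1 at 2.51.

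Genes that MYC is known to activate for cell growth and nucleolar function were lower as a group by camera with a preset correlation (adjusted p = 4.15e-15), but not with an estimated one (adjusted p = 0.573 with an estimated correlation). Of 56 kept members, 16 fell, none rose and 40 did not pass, and 37 were lower when adjusted over the list alone. The median log2 fold change was -0.57, and 54 members had a negative value. NOLC1, a nucleolar phosphoprotein, fell from 138.9 ± 26.0 to 67.5 ± 3.55 TPM (SD, n = 2 each), GRWD1, a ribosome assembly factor, from 39.3 ± 1.06 to 19.8 ± 6.07 TPM, and UNG, the uracil-DNA glycosylase of base excision repair, from 70.5 ± 1.22 to 35.8 ± 5.16 TPM. SORD, which oxidizes sorbitol to fructose and is not a nucleolar gene, fell by 1.16 ± 0.24 on the log2 scale. The list median was -0.55 without control replicate 1 and -0.50 without GD-07 replicate 2. Without limma's trend 3 members were lower. The call of NOLC1 ended without control replicate 1 (limma adjusted p = 0.0574), while SORD and GRWD1 did not pass under quantile normalization or without the trend.

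A broader list of 72 genes often reported as activated by MYC, covering translation factors, chaperonins, splicing factors and replication genes, was lower as a group (camera adjusted p = 1.52e-05, and adjusted p = 0.623 with an estimated correlation). In it 3 genes fell, none rose and 69 did not pass, against 10 lower and 1 higher when adjusted over the list alone, with a median of -0.26. MCM7, a subunit of the replicative helicase, fell from 287.1 ± 4.13 to 145.3 ± 33.1 TPM (SD, n = 2 each), MCM2 from 118.8 ± 11.1 to 71.9 ± 10.6 TPM, and EIF4E, which binds the mRNA cap, from 96.4 ± 4.08 to 62.6 ± 2.44 TPM. Among 17 kept genes reported as repressed by MYC, TXNIP, an inhibitor of glucose uptake, rose by a log2 fold change of 1.22 ± 0.24 (limma adjusted p = 0.0298) and 16 did not pass, with the same count when adjusted over the list alone (camera adjusted p = 0.259). Without control replicate 1 only MCM7 of the 72 genes passed by limma, without GD-07 replicate 1 there were 23 lower and 2 higher, and without GD-07 replicate 2 there were 12 lower and 1 higher. MCM2 and EIF4E ended under median-ratio and quantile scaling and without control replicate 1 (limma adjusted p = 0.222 and 0.291), and EIF4E also without control replicate 2 (0.122).

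Glycolytic genes were lower with GD-07 by camera with a preset correlation (adjusted p = 2.36e-05), but the list did not pass with an estimated one (adjusted p = 0.573 with an estimated correlation) or by fry (0.166). Of 25 kept members of the glycolysis and lactate export list, 5 fell, none rose and 20 did not pass, and 11 were lower when adjusted over the list alone. PGK1, which makes ATP in the payoff phase, fell from 149.1 ± 14.1 to 56.9 ± 8.81 TPM (SD, n = 2 each), a log2 fold change of -1.38 ± 0.16 (limma adjusted p = 0.0109). The lactate exporter SLC16A3 fell by 0.88 ± 0.19 on the log2 scale (limma adjusted p = 0.0374). LDHA, which converts pyruvate to lactate, fell from 501.2 ± 19.4 to 313.9 ± 25.2 TPM (limma adjusted p = 0.0376). PFKP, a phosphofructokinase, fell from 85.5 ± 7.05 to 52.6 ± 7.16 TPM (limma adjusted p = 0.0428) and PKM, a pyruvate kinase, from 1242 ± 7.56 to 767.0 ± 112.2 TPM (limma adjusted p = 0.0497). The other genes fixed for this comparison did not pass. Their log2 fold changes were -0.66 ± 0.17 for ENO1 (limma adjusted p = 0.0531), -0.73 ± 0.21 for PFKFB3 (0.0741), -0.60 ± 0.28 for HK2 (0.215), -0.58 ± 0.24 for PDK1 (0.173), -0.49 ± 0.26 for the glucose transporter SLC2A1 (0.278) and -0.04 ± 0.23 for SLC16A1 (0.941). HK2 was at 9.87 and 8.49 TPM in the controls and at 4.02 and 7.93 TPM with GD-07. Without GD-07 replicate 2 the log2 fold changes were -0.91 (SLC2A1), -1.02 (HK2), -0.92 (PFKFB3), -0.60 (ENO1), -0.88 (PDK1) and -0.39 (SLC16A1). Without GD-07 replicate 1 they were -0.07 (SLC2A1), -0.19 (HK2), -0.53 (PFKFB3), -0.73 (ENO1), -0.28 (PDK1) and 0.32 (SLC16A1).

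The glycolysis list had a median log2 fold change of -0.46. The number of members lower was 1 without control replicate 1, 2 without control replicate 2, 9 without GD-07 replicate 1, 14 without GD-07 replicate 2 and 2 without limma's trend. Only PGK1 kept its call in every one of these 4 limma fits, whereas LDHA, PFKP, PKM and SLC16A3 had adjusted p between 0.0889 and 0.328 without control replicate 1 and between 0.0502 and 0.241 without control replicate 2. LDHA did not pass under median-ratio or quantile scaling, PKM under median-ratio scaling or with a pseudocount of 0.1 or 5 TPM, and PFKP under quantile normalization, and none of these 3 passed without the trend.

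**Figure D2:**
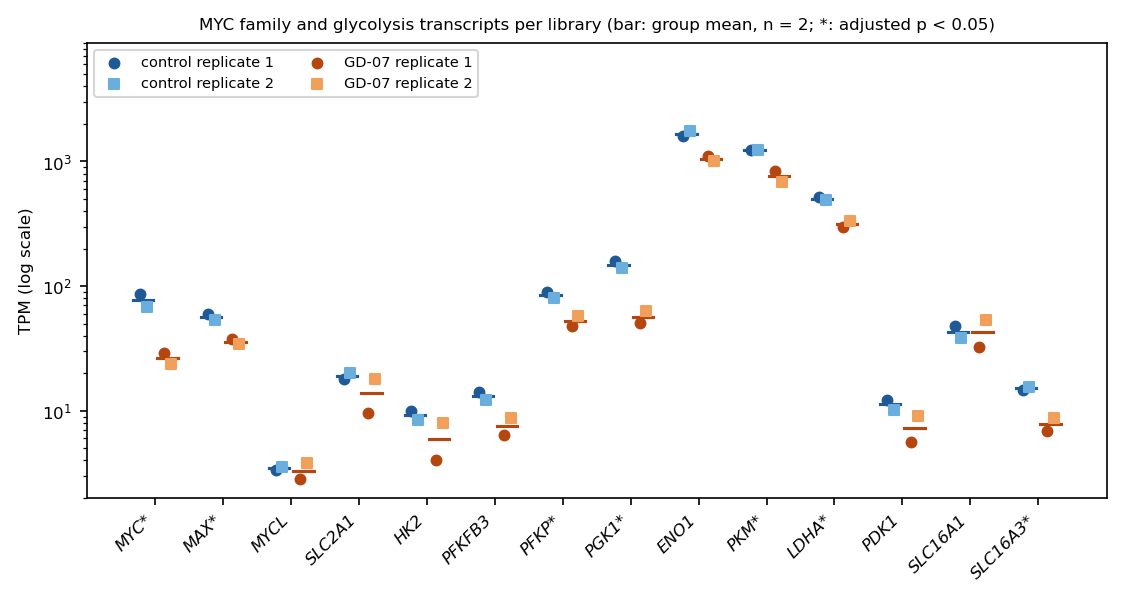
TPM (y axis, log scale) of MYC, MAX, MYCL and glycolysis genes (x axis) in each library, with circles for replicate 1, squares for replicate 2 and bars for group means (n = 2). MYC was at 86.0 and 67.5 TPM in the controls and 29.1 and 23.6 TPM with GD-07, while for SLC16A1 the libraries of the groups overlapped.

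Neighbouring biosynthetic pathways were lower as well. Of 18 kept nucleotide synthesis genes, 5 fell, none rose and 13 did not pass (9 lower when adjusted over the list alone), all 18 had negative values, and the median was -0.46 (camera adjusted p = 3.71e-06, and adjusted p = 0.573 with an estimated correlation). PFAS and PAICS of purine synthesis fell by 1.03 ± 0.16 and 0.73 ± 0.14 on the log2 scale, and CTPS1, which makes CTP, fell from 70.7 ± 4.28 to 36.9 ± 2.16 TPM (SD, n = 2 each). Of 15 pentose phosphate and serine-glycine genes, 5 fell and 10 did not pass, with the same count when adjusted over the list alone. PHGDH, the first enzyme of serine synthesis, fell from 122.6 ± 13.2 to 51.4 ± 15.9 TPM and the mitochondrial folate enzyme MTHFD2 from 210.0 ± 56.2 to 100.1 ± 20.7 TPM (list camera adjusted p = 0.014, and adjusted p = 0.623 with an estimated correlation). Without control replicate 1, 2 nucleotide genes and 1 pentose phosphate or serine-glycine gene passed in limma, and the calls of MTHFD2 and PAICS ended (adjusted p 0.0889 and 0.173). Without control replicate 2, 3 nucleotide genes passed and PAICS did not (adjusted p 0.0543), without GD-07 replicate 1 there were 10, and MTHFD2 did not pass under quantile normalization.

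Of 22 tricarboxylic acid cycle genes, DLAT of the pyruvate dehydrogenase complex fell from 29.4 ± 0.00596 to 14.5 ± 1.36 TPM (SD, n = 2 each), 21 did not pass, and 3 were lower when adjusted over the list alone. The list median was -0.23 (camera adjusted p = 0.00678, and adjusted p = 0.573 with an estimated correlation), and the list did not pass without control replicate 2 (camera adjusted p = 0.093). No gene of glutamine and amino acid uptake passed among 13, with 2 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.603). Over all genes 1 was lower without control replicate 2, 3 were higher without GD-07 replicate 1, and 1 was higher and 2 lower without GD-07 replicate 2. Of 42 nuclear-encoded oxidative phosphorylation genes, cytochrome c (CYCS) fell from 233.3 ± 14.5 to 125.8 ± 6.09 TPM and 41 did not pass, against 4 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.421). None of 55 cytosolic ribosomal protein genes passed, over all genes or adjusted over the list alone (camera adjusted p = 0.282). The oxidative phosphorylation and ribosomal protein lists passed as higher without control replicate 2 (camera adjusted p = 0.0176 and 0.0454) and without GD-07 replicate 2 (0.000905 and 0.000553). Without GD-07 replicate 1 they had 5 higher and 8 lower, and 2 higher and 4 lower, in that order. The cycle list had 6 lower without GD-07 replicate 1 and 3 without GD-07 replicate 2.

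None of the 13 mitochondrially encoded transcripts passed, over all genes or adjusted over the list alone. The median was -0.06, whereas camera placed the list on the higher side (adjusted p = 0.927). These transcripts differed more between the GD-07 replicates than between the groups. MT-ND5 was at 1683 and 1665 TPM in the controls and at 781 and 1569 TPM with GD-07, and MT-ND3 was at 1258 and 1343 TPM in the controls and at 1247 and 2949 TPM with GD-07. Camera placed the list lower without GD-07 replicate 2 (median -0.75) and higher without GD-07 replicate 1, each fit leaving 1 GD-07 library. The log2 fold change of MT-ND5 was -1.10 without GD-07 replicate 2 and -0.09 without GD-07 replicate 1. That of MT-ND3 was -0.06 and 1.18, in the same order. The direction given by camera was lower after median-ratio rescaling (adjusted p = 0.995) and quantile normalization (0.624), neither passing.

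Proliferation genes were lower. Of 36 kept DNA replication and S phase genes, 4 fell, none rose and 32 did not pass, against 19 lower when adjusted over the list alone, with a median of -0.43 (camera adjusted p = 4.77e-07, and adjusted p = 0.573 with an estimated correlation). CDC6, which loads the replicative helicase, fell from 39.1 ± 5.11 to 16.5 ± 1.59 TPM (SD, n = 2 each), and POLA1, the catalytic subunit of DNA polymerase alpha, fell by 1.15 ± 0.24 on the log2 scale. Of 37 genes of mitosis and its preparation, 4 fell, none rose and 33 did not pass, against 9 lower when adjusted over the list alone, with a median of -0.29 (camera adjusted p = 2.98e-05, and adjusted p = 0.707 with an estimated correlation). The spindle motor KIF11 fell from 26.0 ± 5.08 to 10.8 ± 0.0269 TPM, the checkpoint kinase BUB1B from 66.5 ± 21.1 to 29.5 ± 2.18 TPM and the proliferation marker MKI67 from 45.9 ± 12.9 to 23.0 ± 1.85 TPM. Without control replicate 1 each list had 1 member lower, and POLA1, BUB1B and MKI67 had limma adjusted p of 0.208, 0.0889 and 0.22. Without GD-07 replicate 1 each had 11 lower, without GD-07 replicate 2 they had 12 and 8, and without control replicate 2 the mitosis list had 6.

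Other growth control lists did not pass as groups. None of 22 p53 targets passed, over all genes or adjusted over the list alone (camera adjusted p = 0.69). MDM2, a p53 target that degrades p53, had a log2 fold change of 0.78 ± 0.20 (limma adjusted p = 0.0581). It was 1.07 and passed without GD-07 replicate 1 (limma adjusted p = 0.0019), where the list had 2 higher and 1 lower, and 0.49 without GD-07 replicate 2 (0.103), where 1 was higher. Of 18 apoptosis regulators, CYCS and BID, a pro-apoptotic BCL2 family member, fell and 16 did not pass, with the same count when adjusted over the list alone (camera adjusted p = 0.421). BID fell by 0.86 ± 0.20 on the log2 scale (limma adjusted p = 0.0418) and did not pass under median-ratio or quantile scaling. Of 15 replication-dependent histone genes, the linker histone HIST1H1E fell from 2.14 ± 0.234 to 0.580 ± 0.157 TPM and 14 did not pass, against 2 lower and 1 higher when adjusted over the list alone. The list's median (0.01) and camera direction (lower, adjusted p = 0.675) differed in sign. Camera placed the list lower without GD-07 replicate 1 and higher without GD-07 replicate 2, where its median was 0.24. HIST1H1E did not pass without control replicate 1 (limma adjusted p = 0.237) or without control replicate 2 (0.0569), and poly(A) selection leaves most histone mRNA unmeasured. The histone list had 3 lower without GD-07 replicate 1.

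Several stress genes rose without a shift of their whole lists. DDIT3 (CHOP), a transcription factor of the integrated stress response, rose from 31.8 ± 1.22 to 83.0 ± 0.327 TPM (SD, n = 2 each), a log2 fold change of 1.36 ± 0.14 (limma adjusted p = 0.0106). ATF5 rose from 47.5 ± 1.82 to 104.7 ± 7.18 TPM and the glutathione-degrading enzyme CHAC1 from 33.7 ± 1.55 to 57.1 ± 0.967 TPM, whereas the tryptophanyl-tRNA synthetase WARS fell from 173.6 ± 19.1 to 100.4 ± 3.03 TPM. In this list 3 of 19 genes rose, 1 fell and 15 did not pass, against 3 higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.603). The number lower was 0 without control replicate 1, 1 without control replicate 2, 3 without GD-07 replicate 1 and 4 without GD-07 replicate 2. HSPA5 (BiP), the main chaperone of the endoplasmic reticulum, rose from 129.0 ± 4.08 to 270.8 ± 94.9 TPM and was the only one of 19 chaperone and unfolded protein response genes to pass, against 4 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.1). CHAC1 and WARS did not pass without control replicate 1 (limma adjusted p = 0.0813 and 0.18), nor CHAC1 without control replicate 2 (0.0953). HSPA5 did not pass under quantile normalization, and its log2 fold change of 1.02 became 0.66 without GD-07 replicate 2, while without GD-07 replicate 1 the chaperone list passed as higher (camera adjusted p = 0.0142), with 6 higher and 2 lower.

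Of 5 kept metallothioneins and zinc response genes, 2 rose and 3 did not pass, against 3 higher when adjusted over the list alone. The median log2 fold change was 0.61, against 0.35 without GD-07 replicate 2 and 0.12 over 9 members with no filter. The metal-binding MT1X rose from 10.2 ± 1.23 to 26.0 ± 7.75 TPM (SD, n = 2 each) and MT1A from 1.94 ± 0.412 to 6.01 ± 1.08 TPM. Metallothionein genes are close copies whose reads can be shared, so single members are uncertain. The list passed camera (adjusted p = 0.0201, and adjusted p = 0.707 with an estimated correlation), but not under quantile normalization (0.0615) or by camera on ranks (0.0926), and MT1A did not pass without control replicate 1 (limma adjusted p = 0.0535). None of 14 heat shock genes (camera adjusted p = 0.167) and none of 14 hypoxia genes (0.534) passed, over all genes or adjusted over the list alone. Of 16 NRF2 and glutathione genes 1 fell and 15 did not pass, with the same count when adjusted over the list alone, and the list's median (-0.04) and camera direction (higher, adjusted p = 0.888) differed in sign. Without GD-07 replicate 1 camera placed the heat shock list lower (adjusted p = 0.0219), with 4 members lower, and the hypoxia list higher (0.00949), with 4 higher. Without GD-07 replicate 2 the heat shock list had 1 lower and the hypoxia list 3 lower.

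Fatty acid synthesis genes (camera adjusted p = 0.00446, and adjusted p = 0.802 with an estimated correlation) and cholesterol synthesis and uptake genes (0.00115, and adjusted p = 0.623 with an estimated correlation) were lower. FASN, the fatty acid synthase, fell from 182.3 ± 38.0 to 73.4 ± 0.298 TPM (SD, n = 2 each), a log2 fold change of -1.29 ± 0.17 (limma adjusted p = 0.0129), and the desaturase FADS2 fell from 192.8 ± 20.6 to 118.1 ± 3.87 TPM. In this list of 13 fatty acid synthesis genes, 2 fell, none rose and 11 did not pass, against 5 lower when adjusted over the list alone (median -0.40). Of 23 cholesterol synthesis and uptake genes, HMGCS1 fell from 58.3 ± 12.1 to 27.1 ± 2.22 TPM, TM7SF2, a sterol reductase, rose from 38.6 ± 0.715 to 61.3 ± 2.69 TPM and 21 did not pass, against 7 lower and 1 higher when adjusted over the list alone (median -0.38). The fatty acid list did not pass without GD-07 replicate 1 (camera adjusted p = 0.0727), where it had 4 members lower, and it had 1 lower without control replicate 1 (median -0.26), 4 without control replicate 2 and 8 without GD-07 replicate 2. The cholesterol list had no call without control replicate 1, 3 lower without control replicate 2, 4 without GD-07 replicate 1 and 8 without GD-07 replicate 2. Without control replicate 1, limma adjusted p was 0.28 for FADS2, 0.0574 for HMGCS1 and 0.171 for TM7SF2, and 0.144 for TM7SF2 without control replicate 2.

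Autophagy and lysosome genes were higher (camera adjusted p = 1.52e-05, and adjusted p = 0.573 with an estimated correlation). Of 19 kept members, 4 rose, none fell and 15 did not pass, against 11 higher and 1 lower when adjusted over the list alone, and the median log2 fold change was 0.43. NEU1, a lysosomal sialidase, rose from 26.0 ± 2.72 to 61.9 ± 5.04 TPM (SD, n = 2 each), and the autophagy genes GABARAPL1 and WIPI1 from 12.7 ± 1.28 to 24.6 ± 2.14 TPM and from 8.39 ± 0.107 to 15.4 ± 0.526 TPM. The number of members higher was 2 without control replicate 1, 3 without control replicate 2, 9 without GD-07 replicate 1 and 4 without GD-07 replicate 2. WIPI1 did not pass without control replicate 1 (limma adjusted p = 0.141), nor GABARAPL1 and WIPI1 without control replicate 2 (0.0705 and 0.111).

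Genes of growth factor signalling and of the contractile, matrix-associated state were lower in part. Of 17 immediate early genes, 3 fell, none rose and 14 did not pass, against 6 lower when adjusted over the list alone (median -0.24, camera adjusted p = 0.00773, and adjusted p = 0.802 with an estimated correlation). ETV4, a transcription factor downstream of ERK, fell from 47.2 ± 0.526 to 21.1 ± 0.420 TPM (SD, n = 2 each), SPRY4, a feedback inhibitor of that pathway, from 16.2 ± 3.09 to 6.48 ± 0.645 TPM and IER3 from 198.5 ± 8.72 to 110.7 ± 6.23 TPM. Of 17 mesenchymal and matrix genes, 2 fell and 15 did not pass, against 5 lower when adjusted over the list alone (median -0.23, camera adjusted p = 0.0331, and adjusted p = 0.802 with an estimated correlation). These were TAGLN, an actin-binding protein of contractile cells, from 320.6 ± 33.8 to 118.5 ± 26.1 TPM, and CYR61, a matrix-associated signalling protein, from 27.6 ± 4.76 to 12.5 ± 3.15 TPM. Without GD-07 replicate 1 neither list passed (camera adjusted p = 0.0747 and 0.313), and without GD-07 replicate 2 they had 7 and 6 members lower. The mesenchymal list had 1 lower without control replicate 1 and 3 without either control replicate 2 or GD-07 replicate 1. Its median was -0.43 without either control replicate 2 or GD-07 replicate 2, -0.12 without GD-07 replicate 1 and -0.48 with a filter at a mean of 5 TPM, and that of the immediate early list was -0.38 without control replicate 2 and -0.14 with a pseudocount of 5 TPM. The 7 kept fibroblast markers, which share COL1A1 with the mesenchymal list, had a median of -0.42 and did not pass (camera adjusted p = 0.128). Without control replicate 1, SPRY4 and CYR61 did not pass (limma adjusted p of 0.0578 for each), and the mesenchymal list did not pass with no filter (camera adjusted p = 0.115) or by camera on ranks (0.0682).

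Of 8 kept NF-kappaB and inflammatory genes none passed over all genes, while 7 were lower when adjusted over the list alone. RELB, an NF-kappaB subunit, had a log2 fold change of -0.75 ± 0.20 (limma adjusted p = 0.0627) and TNFAIP2 of -0.79 ± 0.23 (0.0793). The list's median was -0.60 and it passed camera (adjusted p = 0.00943, and adjusted p = 0.573 with an estimated correlation), but not with a filter at a mean of 5 TPM (0.139, median -0.41 over 5 members). The median was -0.35 with a pseudocount of 5 TPM and -0.12 over 18 members with no filter. Without GD-07 replicate 1, 3 members passed as lower, among them RELB (-0.92, limma adjusted p = 0.0238) and TNFAIP2 (-1.02, 0.0104), and without GD-07 replicate 2 there was 1. Of 14 interferon response genes, IFI6 rose from 27.0 ± 3.87 to 65.4 ± 7.79 TPM (SD, n = 2 each), 1 gene fell and 12 did not pass, with the same count when adjusted over the list alone (camera adjusted p = 0.128). Of 4 kept epithelial genes, the tight junction gene CLDN7 fell from 2.44 ± 0.111 to 0.628 ± 0.209 TPM, and adjusted over the list alone 1 was higher and 1 lower. None of 4 aryl hydrocarbon receptor targets passed, the largest being ALDH1A3 at -0.70 ± 0.23 (limma adjusted p = 0.101), while CYP1B1 was at -0.54 ± 0.21 (0.154). Without GD-07 replicate 2 these were -0.83 and -0.79, and without GD-07 replicate 1 they were -0.56 and -0.30. CLDN7 did not pass without control replicate 1 (limma adjusted p = 0.135), where no interferon response gene was lower.

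Over the 31 lists with at least 5 kept members, 15 passed camera with the preset correlation of 0.01, 13 lower and 2 higher, and 19 passed without GD-07 replicate 2. None passed with an estimated correlation (smallest adjusted p = 0.573) or by fry's directional test (smallest adjusted p = 0.135), while 21 passed fry's test of change in either direction. With so few libraries the estimated version has little power. The tricarboxylic acid cycle list had an estimated correlation of -0.000572, below the preset, yet its unadjusted camera p rose from 0.00219 to 0.0779.

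**Figure D3:**
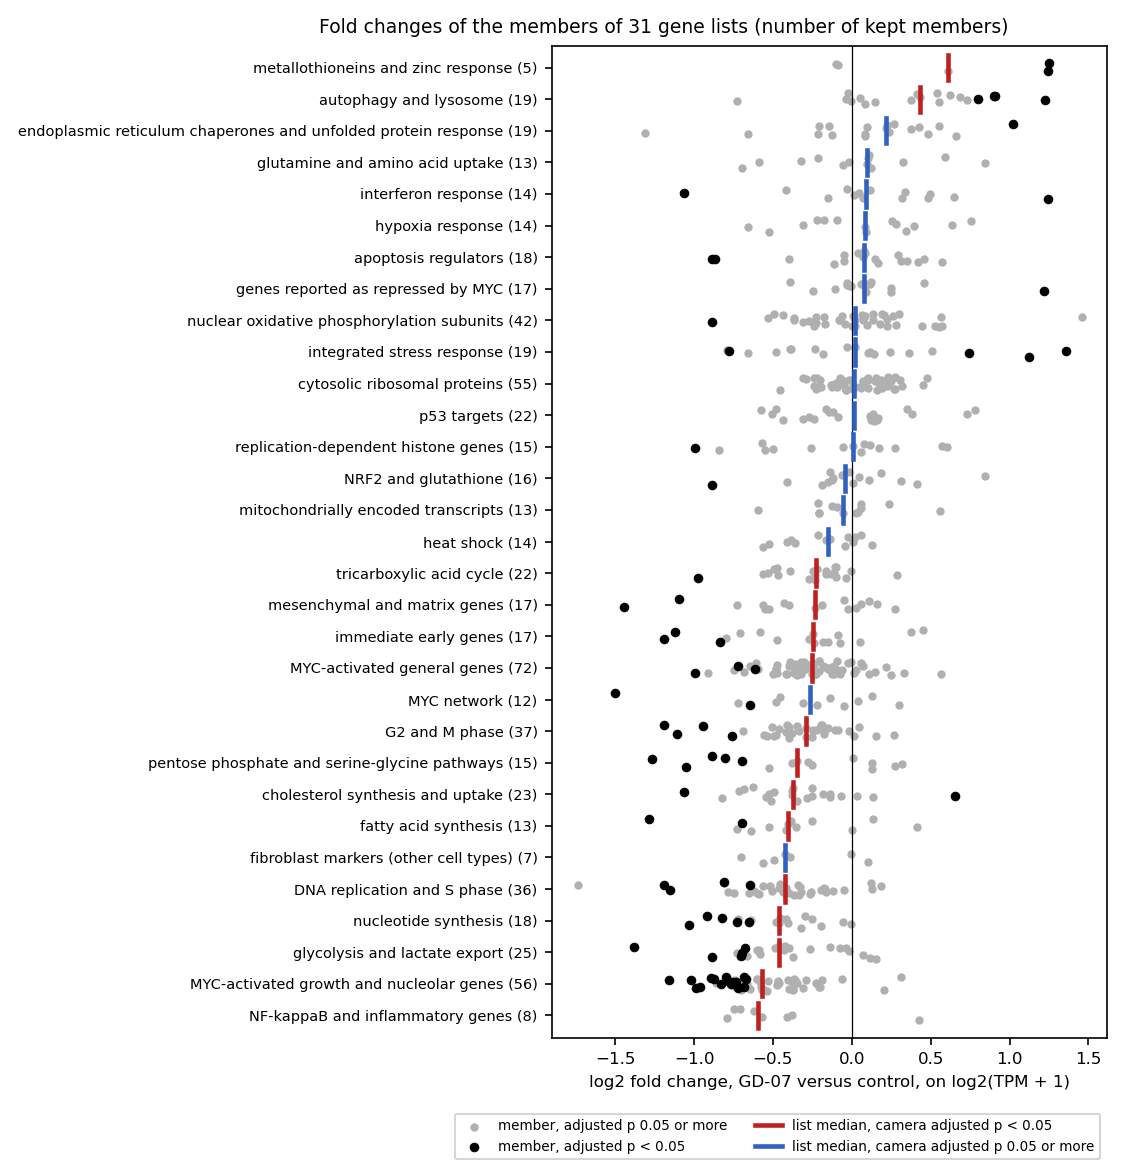
Log2 fold changes on log2(TPM + 1) (x axis) of each kept member of 31 gene lists (y axis, kept members in parentheses), black where limma's adjusted p was under 0.05, with a bar at each list's median, red where camera passed with the preset correlation. Medians of kept members ran from -0.60 for NF-kappaB and inflammatory genes to 0.61 for metallothioneins, which with no filter were -0.12 and 0.12, and the latter was 0.35 without GD-07 replicate 2.

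The largest single changes lay outside these lists. PRKDC, the catalytic subunit of DNA-dependent protein kinase, fell from 40.6 ± 12.3 to 3.93 ± 2.69 TPM (SD, n = 2 each), a log2 fold change of -3.16 ± 0.36 (limma adjusted p = 0.0109), and lies on chromosome 8 from 47773108 to 47960183 in GRCh38. MYH10, a non-muscle myosin heavy chain, fell from 45.1 ± 21.8 to 9.21 ± 2.10 TPM and BCL9L, a beta-catenin coactivator, from 3.72 ± 2.25 to 0.0603 ± 0.0373 TPM. PPT1, a lysosomal palmitoyl-protein thioesterase on chromosome 1 from 40071461 to 40097727, rose from 5.51 ± 0.328 to 36.3 ± 6.55 TPM, a log2 fold change of 2.51 ± 0.19 (limma adjusted p = 0.00271). CEMP1, CRELD1 and NKRF, a repressor of NF-kappaB, rose by log2 fold changes of 2.11, 1.82 and 1.75. NKRF did not pass without control replicate 1 (limma adjusted p = 0.0505, log2 fold change 1.11), under quantile normalization, with a pseudocount of 0.1 TPM, with a robust prior or without limma's trend, and BCL9L was not kept by the filter without that library.

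The other entries with the largest changes were pseudogenes or clone-named loci, whose reads can be shared with close copies, so their values are uncertain. The dihydrofolate reductase pseudogene DHFRP1 was at 5.88e-09 and 0 TPM in the controls and at 3.01 and 11.7 TPM with GD-07, AP001052.1, CTD-2192J16.22 and CTD-2510F5.6 rose, and CKS1BP3, OR5AK4P, AC090094.1, AC006486.9 and RP11-651P23.4 fell. CKS1BP3 was at 92.2 and 19.8 TPM in the controls and at 2.77 and 3.80 TPM with GD-07. DHFRP1, CKS1BP3 and CTD-2510F5.6 did not pass with a robust prior, nor CTD-2510F5.6 under quantile normalization, with a pseudocount of 0.1 TPM or without limma's trend. Among abundant genes that passed, the actin-sequestering TMSB10 rose from 1665 ± 274.2 to 3005 ± 259.0 TPM (SD, n = 2 each), the translation initiation factor EIF1 from 657.9 ± 14.4 to 1124 ± 78.1 TPM and the laminin subunit LAMB2 from 460.9 ± 15.3 to 804.8 ± 108.9 TPM. EIF5A, a translation factor, fell from 678.9 ± 10.2 to 413.3 ± 66.8 TPM and the clone-named AC010970.2 from 1056 ± 129.2 to 328.3 ± 68.4 TPM. TMSB10, EIF1, LAMB2 and EIF5A did not pass under median-ratio scaling, nor without control replicate 1 (limma adjusted p between 0.162 and 0.518) or control replicate 2 (between 0.132 and 0.166).

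Markers of other cell types were mostly low. None of 8 endothelial markers reached a mean of 1 TPM, and of 12 leukocyte markers 2 did, neither passing limma's test, among them CD68 at 5.75 ± 1.35 TPM in the controls (SD, n = 2, adjusted p = 0.332). Of 9 keratinocyte markers only SFN was kept, at 4.66 ± 0.175 TPM in the controls and 2.06 ± 0.563 TPM with GD-07 (limma adjusted p = 0.0501). As the only kept member it has no adjustment over the list alone, which leaves its unadjusted limma p of 0.0027. Its log2 fold change was -0.90, against -1.09 without GD-07 replicate 1 and -0.71 without GD-07 replicate 2. Of 9 hepatocyte markers only FGB was kept (limma adjusted p = 0.892). None of 7 kept fibroblast markers passed, over all genes or adjusted over the list alone (camera adjusted p = 0.128), although 6 had negative values and the median was -0.42, with COL1A1 at 35.1 ± 5.53 TPM in the controls and 24.0 ± 8.56 TPM with GD-07. Without GD-07 replicate 2 the fibroblast list passed as lower (camera adjusted p = 0.00931, median -0.64) with 2 members lower, and COL1A1 passed (-0.92, limma adjusted p = 0.00128). The median was -0.27 without control replicate 1 and -0.17 without GD-07 replicate 1, and with no filter the list passed (camera adjusted p = 0.041).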

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

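The GC correction, the restriction to protein-coding genes, the collapse of identical symbols and the crossed block were chosen only after the results were seen, and the other settings were planned. The number of genes changed was 681 (264 higher, 417 lower). With no filter it was 0, with 0 higher and 0 lower in limma, against 3970 at an unadjusted p under 0.05, and this setting tests 26773 genes, many near 0. It was 385 (158 higher, 227 lower) without the trend, 1039 (419 higher, 620 lower) after GC correction, 1168 (446 higher, 722 lower) among protein-coding genes, 6 (1 higher, 5 lower) at an adjusted p under 0.01 and 265 (106 higher, 159 lower) at 2-fold or more. The last pair are stricter by construction, and for the others the cause was not tested. Leaving out each library gave 286 to 2308 genes, 141 to 903 higher and 145 to 1405 lower. All of the 681 genes that a setting tested kept their sign in it. They were selected for their difference in these same libraries, so this agreement was nearly fixed in advance and is not separate support. With the replicate block the number of genes changed was 912 (320 higher, 592 lower), and the MYC network list passed (camera adjusted p = 0.0318). Of the named genes PKM, TMSB10 and WIPI1 did not pass with this block while GLUL and MDM2 did. Deviations of same-numbered libraries from their group means correlated at -0.279 across genes, so the numbers are not read as pairs, and a crossed replicate block gave 2934 (1198 higher, 1736 lower).

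Of 31 lists tested, 15 passed camera, 0 passed with an estimated correlation and 0 by fry, while 21, among them lists that camera did not call, passed fry's test of change in either direction. These adjusted p were 0.573 and 0.135 for MYC-activated growth and nucleolar genes, 0.623 and 0.166 for MYC-activated general genes, and 0.573 and 0.166 for glycolysis. The few residual degrees of freedom bear on the version with an estimated correlation, and for fry the cause was not tested. Other settings gave between 13 and 19 lists.

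The remaining reversals concern lists and genes that did not pass, and the cause was not tested. The mitochondrially encoded list reversed after median-ratio rescaling (camera adjusted p = 0.995), quantile normalization (0.624), GC correction (0.911) and by fry (0.976), and ran from 1.03e-10 to 0.98 when a library was left out. By fry p53 targets (0.976) and NRF2 genes (0.918) reversed, as did histone genes with a filter at 5 TPM (0.84). When a library was left out, camera adjusted p ran from 0.136 to 0.98 for glutamine uptake, 0.000905 to 0.434 for oxidative phosphorylation, 0.000553 to 0.607 for ribosomal proteins, 0.649 to 0.855 for NRF2 genes, 0.00949 to 0.465 for hypoxia genes and 0.126 to 0.92 for histone genes. The log2 fold change of SLC16A1 was 0.0505 under quantile normalization and -0.39 to 0.32 when a library was left out, that of MYCL -0.21 to 0.10 and that of MT-ND3 -0.0594 to 1.18. Over all settings, named genes held their side of the threshold and direction in 1605 of their comparisons, lost the call in 206, gained it in 88 and reversed in 5, and lists did so in 580, 39, 12 and 17.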

Other observations

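The gene groups and genes of the next 2 paragraphs were chosen after their values were seen, as were the test on other lysosomal proteins and the rescaling test of the MYC-activated list, while the other tests weighed here were set out before their results were seen. Of 21 further lists and symbol families tested, 12 passed camera, 9 did not (among them tubulins, proteasome subunits, kinesins, RAB GTPases and collagens), and none passed with an estimated correlation (smallest adjusted p = 0.577). Those that passed include large families grouped only by symbol. These were 178 TMEM genes (median 0.12, camera adjusted p = 0.00228) and 414 ZNF genes (median 0.11, camera adjusted p = 0.0102). Camera at the preset correlation thus also called lists with small medians. Genes of the actin cytoskeleton and contractile machinery were lower with GD-07. Of 32 kept genes 11 fell, 1 rose and 20 did not pass, and the median log2 fold change was -0.51 ± 0.14 (camera adjusted p = 3.09e-07, and adjusted p = 0.577 with an estimated correlation). The list holds TAGLN and MYH10, whose falls are given above and had already been seen, so its camera result is not separate support. The 7 kept fibroblast markers had a median of -0.42 and did not pass (camera adjusted p = 0.128). CNN1, a smooth muscle calponin, fell from 117.9 ± 2.57 to 42.2 ± 3.39 TPM (SD, n = 2 each), a log2 fold change of -1.46 ± 0.14 (limma adjusted p = 0.00695). ACTN1, an actin crosslinker, fell from 94.3 ± 24.9 to 37.0 ± 3.15 TPM and the myosin light chain MYL7 from 11.3 ± 0.375 to 2.38 ± 1.15 TPM. ACTB rose from 151.7 ± 39.3 to 307.4 ± 64.5 TPM, but these levels are low for this gene and its reads can be shared with close copies. Of 20 aminoacyl-tRNA synthetases, which charge tRNAs, AARS, GARS, IARS, VARS and WARS fell (camera adjusted p = 0.0435, and adjusted p = 0.745 with an estimated correlation). The family was split, with 13 negative and 7 positive values and a median of -0.30 ± 0.16, and none passed as higher. WARS also belongs to the integrated stress response list. AARS fell from 225.2 ± 7.46 to 131.0 ± 6.22 TPM and VARS from 70.8 ± 4.34 to 38.8 ± 3.50 TPM.

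Subunits of the RNA polymerases that transcribe ribosomal and transfer RNA genes were lower, with 2 of 14 past the threshold and 13 with negative values (median -0.52 ± 0.10, camera adjusted p = 0.000722, and adjusted p = 0.745 with an estimated correlation). Of 20 nucleoporins 3 fell (median -0.32 ± 0.07, camera adjusted p = 0.00488, and adjusted p = 0.762 with an estimated correlation). Subunits of the vacuolar ATPase, which acidifies lysosomes, were higher, with ATP6V0A1 past the threshold and 17 of 19 with positive values (median 0.28 ± 0.09, camera adjusted p = 0.000722, and adjusted p = 0.577 with an estimated correlation). Among 12 kept major histocompatibility genes, HLA-F, HLA-DRB1 and HLA-DQB1 rose, while B2M, the light chain of class I molecules, fell from 219.3 ± 39.3 to 69.2 ± 46.4 TPM (SD, n = 2 each). The GD-07 replicates differed for B2M, at 102.0 and 36.4 TPM, and the list (camera adjusted p = 0.0233, and adjusted p = 0.745 with an estimated correlation) did not pass without GD-07 replicate 2 (0.241).

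The lower level of MYC-activated growth and nucleolar genes is the first pattern weighed. Median log2 fold change fell along deciles of gene GC content from 0.04 to -0.16, yet after GC correction the list's median was -0.548 ± 0.0367 (bootstrap SE, 56 genes), which argues against that trend as the whole cause. GC trends were also present within the groups. From the lowest to the highest decile, GD-07 replicate 2 minus replicate 1 ran from 0.256 to -0.125, and control replicate 2 minus replicate 1 from -0.222 to -0.0362. The median of all genes was -0.04, against -0.57 for the list, so a shift of TPM values shared by all genes was too small to be the whole cause. After median-ratio rescaling, which removes such a shift, the list's median was -0.539 ± 0.0549. With so small a median of all genes the rescaling could move the list only a little, so it adds no separate evidence. Because TPM is scaled to each library's total, a change of total RNA shared by all genes cannot be seen in these values and stays open. Without GD-07 replicate 2 the list's median was -0.503 ± 0.0382, which argues against that library alone. The GD-07 treatment itself and other differences between the cultures or library preparations of the groups stay open, and 2 libraries against 2 make 3 splits, too few for a share under 0.05: 1 of 3, the real split, gave 681 genes, and the highest of the others gave 0.

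The second pattern is within the GD-07 group. All 13 mitochondrially encoded transcripts were higher in GD-07 replicate 2 than in replicate 1, by 1.68 to 3.94 times, with a median log2 difference of 1.30 ± 0.16, against -0.19 between the controls. That difference was 1.22 ± 0.184 after GC correction and 1.21 ± 0.161 after median-ratio rescaling, which argues against both as the whole cause of the gap between these libraries. The errors resample the 13 transcripts, whose estimated correlation was 0.979, and do not measure variation between libraries. GD-07 replicate 1 was the lowest of the 4 libraries for all 13, and GD-07 replicate 2 the highest for 12, so neither library alone sets the gap. RNA handling or library preparation could differ between these replicates and stays open, and no biological explanation was tested, since the labels give both the same treatment.

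The third pattern is the higher level of autophagy and lysosome genes. After GC correction the list's median was 0.503 ± 0.136 (19 genes) and without GD-07 replicate 2 it was 0.353 ± 0.0723, which argues against the GC trend and that library alone. A wider rise of lysosomal genes is a candidate explanation. Of 43 other lysosomal proteins 8 rose, among them FUCA1, NPC2 and SMPD1, and none fell (camera adjusted p = 1.29e-07, and adjusted p = 0.745 with an estimated correlation). Positive values were held by 38 of them and negative values by 5, so most were higher in these libraries. Their median of 0.292 ± 0.0965 less 2 standard errors was 0.0986, just under the bound of 0.1 set for it. PPT1 was kept out because its rise had already been seen, and with it the value was 0.133. This 1 gene decides the side of the bound, so a wider rise of the size set there stays open.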
